A study of Arabidopsis thaliana with 6 samples.

How the data were processed

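Whole seedlings of Arabidopsis thaliana, 3 libraries of Col-0 wild type and 3 of cfm6-1, were sequenced as 100 bp single-end reads on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name the genome build TAIR10; the aligner, the counting tool and the annotation release are not given in the sources used here, nor is whether counting used strand. The authors deposited RPKM values, rounded to 2 decimals, for all loci of the annotation; the unit was read from the values, which become whole reads when multiplied by gene length and depth, and the column names match the sample titles. A deposited column gives for each locus a fraction from 0 to 1 which, by its name, is the largest share of multiply mapped reads; how the authors computed it is not given. A second table from the authors holds gene model length, a p-value per locus, an adjusted p-value and a log2 fold change, given only at unadjusted p-values up to 0.05 (the base was read from the sizes). That table also has 6 columns of per-library values under codes that the labels do not tie to samples; these 6 columns, and a table of mapping totals with 6 rows under the same codes, were not used here, and the direction of the authors' comparison is that of these codes.

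Depth was estimated from the values: in genes under 0.3 kb with no multiply mapped reads, RPKM times length moves in steps of 1 read, and the depth between 20 and 80 M reads that made the values closest to whole reads was taken for each library. At that depth 100% of the 336 to 376 values used per library were within 0.1 of a whole read. Reads rebuilt this way summed to 44.1 to 49.2 M per library. Replicates of 1 genotype differed by more than sampling noise, with a chi-square of 10.5 to 25.1 per degree of freedom over the pairs, so each library counted as 1 replicate.

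Because the values are RPKM, the test planned for normalized values was used: limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a mean-variance trend, genotype as the single factor and Benjamini-Hochberg adjustment, over the 20047 loci with at least 1 RPKM in at least 3 libraries. A pseudocount of 1 understates the change of low genes, so folds and percentages in the text are ratios of mean RPKM, and log2 changes are the fitted ones. Loci were named by locus tag from a reference table of assembly TAIR10.1, which held 19868 (99.1%) of the tested loci; only names were taken from it. Loci with a multiply mapped share above 0.1 (1333 of those tested) are reported as uncertain where named. On simulated values for this comparison (19670 genes), the fit recovered 41 of 50 genes changed 1.25-fold, 49 of 50 changed 1.5-fold and 50 of 50 changed 2-fold or 4-fold; 9.95% of its 211 calls were false, above the nominal 5%. The simulation gave every gene the same spread between replicates (dispersion 0.00143, a median over genes in wild type) and left all other genes unchanged. Real genes differ in spread and most of them were called, so these rates need not hold for the real values.

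Before the data were examined, 28 gene lists were fixed: mitochondrial genes for complex I, other protein-coding mitochondrial genes, mitochondrial dysfunction stimulon, alternative respiratory pathway, nuclear complex I, complexes III, IV and V, CRM domain family, other mitochondrial splicing and transcription factors, mitochondrial chaperones and proteases, tricarboxylic acid cycle, photorespiration, nuclear photosynthesis, cell cycle, carbon starvation, low-oxygen response, salicylic acid defence, jasmonate, abscisic acid and cold, flavonoids, heat shock, auxin, iron, phosphate starvation, rapid touch and stress response, circadian clock, root markers, seed and embryo markers, and floral organ identity. Some genes stand in more than 1 list. The 26 lists with at least 5 tested members were compared with all other genes by camera (preset correlation 0.01, adjusted over the lists), then with an estimated correlation and with fry, which tests each list by itself; counts of members are given over all genes tested and adjusted over the list alone.

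Named genes followed a rule fixed beforehand: CFM6; the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 RPKM and no overlap between genotypes; up to 4 members per list, in order of adjusted p, or the member of smallest p where none passed; and all nad5 loci. From the list members the text names a part, most often the first of that order. Shares of the mitochondrial and plastid genomes are sums of RPKM times length over loci of each genome, compared by a two-sided exact permutation test. Alternatives were another pseudocount, no filter, replicate blocks, organelle loci left out and each library left out; other scalings, a stricter filter, limma-voom on rebuilt reads and the loss of loci with shared reads were chosen after seeing the data. Planned tests of counts, of exons and introns and of mapping totals were not run, since the values are RPKM per gene model and the mapping totals carry unmatched codes.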

Results

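RNA was sequenced from whole Arabidopsis thaliana seedlings of the Col-0 wild type and of cfm6-1, a line altered in CFM6. CFM6 belongs to the CRM domain proteins, RNA-binding proteins of plants that act in the splicing of group II introns, and the series title places it in the splicing of intron 4 of nad5, a mitochondrial gene for a complex I subunit. The seedlings were 14 days old and grew at 22 °C with 16 h of light and 8 h of dark on medium with 1% sucrose. Each genotype had 3 libraries, called biological replicates in the labels. The table held RPKM values (reads per kilobase of gene model per M reads, where M stands for 1e6) for each locus, and 20047 loci reached 1 RPKM in at least 3 libraries and were tested. The steps between the values of short genes placed the depth at 49.6, 50.5 and 50.6 M reads in wild type replicates 1 to 3, and at 47.3, 52.4 and 52.8 M in cfm6-1 replicates 1 to 3. The comparison asked which transcripts differ between cfm6-1 and wild type seedlings.

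The locus taken as CFM6, AT4G13070, fell to 33.2% of its wild type level. It was at 3.88 ± 0.207 RPKM in wild type and at 1.32, 1.23 and 1.32 in cfm6-1 replicates 1 to 3 (mean ± SD, n = 3). On the log2(RPKM + 1) scale it fell by 1.09 (SE 0.06, limma adjusted p = 1.20e-05). In the authors' deposited table its log2 fold change was -1.63, with an adjusted p of 0.0129. The reference annotation gives this locus a CRM domain product and no symbol, and a line can keep transcripts outside the altered part of a gene, so the level is a check of the labels alone.

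Most of the measured transcriptome differed between the genotypes. Of the 20047 tested genes, 7736 were higher and 6063 lower in cfm6-1 at a limma adjusted p below 0.05, and 1339 of the rises and 947 of the falls reached 1 on the log2 scale. The balance of rises and falls depends on the scaling: it was 6933 and 6873 with median-of-ratios scaling and turned to 6562 and 7248 with quantile normalization. The first principal component held 91.1% of the variance and separated the genotypes. The values of the 3 cfm6-1 libraries lay entirely above or below those of the 3 wild type libraries for 74.3% of tested genes, where chance gives 10%. The authors' deposited table lists 8561 loci at an adjusted p below 0.05, and 7897 of them were also called here, all with the same sign.

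The genes that rose most on the log2(RPKM + 1) scale, which understates the change of low genes, included transcription factors. RRTF1, a redox-responsive transcription factor, went from 0.23 ± 0.07 RPKM to 90.8 ± 33.6 (mean ± SD, n = 3), and DDF1, a transcription factor of the AP2 type, from 0.04 ± 0.08 to 26.0 ± 7.70. CYP94B3, an enzyme that inactivates the jasmonate hormone, rose by 4.63 on the log2(RPKM + 1) scale, and TH8, a thioredoxin, by 4.88. AT5G09570, a Cox19-like CHCH protein, rose from 1.07 ± 0.19 to 50.6 ± 0.96 RPKM. The other loci among the 10 largest rises on this scale have no symbol: AT4G27654, AT5G24640, AT1G67105, AT4G12735 and AT4G27657 rose by 4.70 to 5.75 on that scale. The limma adjusted p of the 10 rises was 3.88e-05 or lower.

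Defence genes were among the 10 largest falls on the same scale, beside genes of other kinds. AT4G33720, a secreted protein of the PR1 superfamily, fell from 113 ± 66.5 to 0.07 ± 0.04 RPKM (n = 3). PCR1 fell from 102 ± 33.8 to 1.05 ± 0.98, and the receptor-like kinase CRK4 from 46.8 ± 4.35 to 0.55 ± 0.22. ACD6, an ankyrin protein that promotes salicylic acid defence, fell from 52.3 ± 7.88 to 0.91 ± 0.25 RPKM. AT2G47880, a glutaredoxin, fell by 5.27 on the log2(RPKM + 1) scale. PCC1 fell by 5.33, though a share of up to 0.354 of its reads was multiply mapped, so its level is uncertain. AT1G21525, AT2G32160, AT3G57460 and AT3G48640 complete the 10 largest falls, with log2 changes between -4.49 and -3.90 and limma adjusted p of 2.54e-05 or lower.

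**Figure D1:**
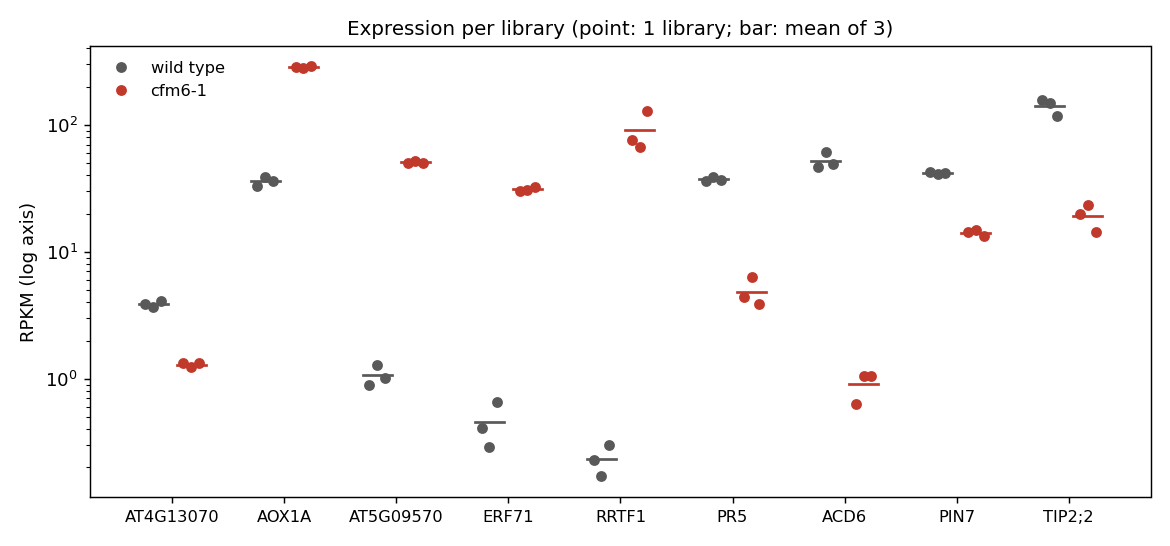
RPKM of 9 named genes on a log axis, with each point 1 library and each bar the mean of 3 libraries of wild type (grey) or cfm6-1 (red). AOX1A lies at 36.1 RPKM in wild type and 284 in cfm6-1, PR5 at 37.3 and 4.85, and the groups do not overlap for any gene shown.

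Transcripts that plants raise when mitochondria fail were the most strongly raised group. Of 20 genes in the mitochondrial dysfunction stimulon list, 19 rose and none fell (19 and 0 adjusted over the list alone), with a median log2 change of 3.05 (camera adjusted p = 8.41e-09). That call is not kept in the stricter form of the test (adjusted p = 0.470 with an estimated correlation). AOX1A, the alternative oxidase that bypasses the cytochrome pathway, rose 7.88-fold, from 36.1 ± 2.99 to 284 ± 3.63 RPKM (n = 3). NAC13, a transcription factor of mitochondrial retrograde signalling, rose 9.26-fold. NDB4, an external alternative NAD(P)H dehydrogenase, was at 0.21 ± 0.08 RPKM in wild type and 28.5 ± 0.67 in cfm6-1. Over the whole alternative respiratory pathway, 7 of 12 genes rose and 3 fell (7 and 3 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.0890). NDB3 and AOX1C also rose, 32.1-fold and 7.93-fold from levels near 0.

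Mitochondrial chaperones and proteases rose in 11 of 12 cases and fell in none (11 and 0 adjusted over the list alone; median 1.15, camera adjusted p = 1.50e-05, and adjusted p = 0.470 with an estimated correlation). mtHsc70-1, the matrix chaperone, rose 4.05-fold, its partner MGE1 4.05-fold and prohibitin PHB1 2.71-fold. In the heat shock list, 10 of 18 genes rose and none fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.00317, and adjusted p = 0.544 with an estimated correlation). AT5G51440, a small heat shock protein that also stands in the stimulon list, rose from 6.09 ± 0.72 to 139 ± 18.4 RPKM, and DREB2A, a regulator of heat and drought genes, rose 6.38-fold. The heat shock list stood apart in cfm6-1 replicate 1: its mean log2(RPKM + 1) lay 0.78 above the mean of cfm6-1 replicates 2 and 3, which were at 3.32 and 3.31, against 2.23, 2.27 and 2.16 in wild type replicates 1 to 3. Without that library the median was 1.09 rather than 1.38, and the camera call stayed (adjusted p = 0.000283). The low-oxygen list had 12 of 19 genes higher and 4 lower (13 and 4 adjusted over the list alone; camera adjusted p = 0.0345, and adjusted p = 0.544 with an estimated correlation). The call is lost with a filter at 10 RPKM (adjusted p = 0.178). Members of this list moved apart: ERF71 rose from 0.45 ± 0.19 to 31.2 ± 1.26 RPKM and HB1, a haemoglobin, 7.82-fold, while ERF73, a close relative of ERF71, fell to 52.4% of wild type.

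Nuclear genes for the respiratory chain also rose, most of them by less than 1 on the log2 scale. Of 40 nuclear complex I subunits, 29 rose and 4 fell (29 and 4 adjusted over the list alone; median 0.29, camera adjusted p = 0.00134, and adjusted p = 0.544 with an estimated correlation). mtACP2, an acyl carrier protein, and GAMMA CA3 rose 1.63-fold and 1.53-fold. Of 32 subunits of complexes III, IV and V, 29 rose and none fell (29 and 0 adjusted over the list alone; median 0.44, camera adjusted p = 4.81e-06, and adjusted p = 0.498 with an estimated correlation), with the smallest adjusted p in the ATP synthase genes AT1G51650 (1.73-fold) and AT5G08690 (1.69-fold). In the tricarboxylic acid cycle, 15 of 18 genes rose and none fell (15 and 0 adjusted over the list alone; median 0.48, camera adjusted p = 0.000149, and adjusted p = 0.498 with an estimated correlation). The aconitase ACO3 rose 2.40-fold, and AT3G55410, a subunit of 2-oxoglutarate dehydrogenase, rose 1.53-fold.

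Other factors of mitochondrial RNA processing also rose, and the CRM family did not move one way. Among 17 other mitochondrial splicing and transcription factors, 13 rose and none fell (13 and 0 adjusted over the list alone; median 0.37, camera adjusted p = 0.000741, and adjusted p = 0.470 with an estimated correlation). The RNA helicases PMH1 and PMH2, which act in mitochondrial intron splicing, rose 3.86-fold and 1.69-fold, and AT5G15700, an organelle RNA polymerase, 2.07-fold. Of 14 CRM domain genes, AT4G13070 included, 4 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.765). CAF2, a chloroplast splicing factor, fell to 62.6% of wild type, and AT2G21350 and AT3G27550 rose 2.25-fold and 2.13-fold. The median (0.05) and mean (0.01) of this list are above 0 while camera, which compares with all other genes, points down, and the median turns to -0.05 after quantile normalization.

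Loci of the mitochondrial genome, most of whose signal came from ribosomal RNA, held 0.0213 ± 0.00352% of the summed signal in wild type and 0.0356 ± 0.00514% in cfm6-1 (n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Without ribosomal RNA loci the shares were 0.00379 ± 0.000369% and 0.00508 ± 0.000592%, 1.34-fold rather than 1.67-fold apart. The plastid genome held 0.195 ± 0.0623% and 0.149 ± 0.0408% (exact permutation p = 0.3). Without ribosomal RNA loci its shares were 0.0270 ± 0.00691% and 0.0193 ± 0.00376% (exact permutation p = 0.3). These shares, and the levels of single organelle loci below, describe the RNA that was sequenced. Whether they follow the amount of organelle RNA in the seedlings was not tested. Of 91 tested plastid loci, 27 were lower and 3 higher in cfm6-1 (median log2 change -0.35), against 30.2% and 38.6% of all tested genes. Multiply mapped shares were above 0.1 at 24 of the 91. Of 5 mitochondrial genes for complex I subunits that could be tested, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.488). Of 6 other protein-coding mitochondrial genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.972), with a median of 0.08 and a mean of 0.02 while camera points down. The gene names used for mitochondrial loci come from the list fixed beforehand, because neither the files nor the reference table pair these loci with names. cox1 (ATMG01360), with no multiply mapped reads, rose from 0.87 ± 0.11 to 1.73 ± 0.31 RPKM (limma adjusted p = 0.00218). nad3 (ATMG00990) went from 1.76 ± 0.46 to 4.62 ± 0.28 RPKM and nad1c (ATMG00516) from 1.31 ± 0.32 to 2.88 ± 0.54, but multiply mapped reads reached shares of 1 and 0.824, so both are uncertain. The same holds for the falls of atp8 (ATMG00480) and atp9 (ATMG01080), with shares of 1 and 0.639; the fall of atp9 also misses the threshold without wild type replicate 1 (adjusted p = 0.0513) or replicate 2 (adjusted p = 0.0505).

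The 3 loci of nad5 were at low levels, and ATMG00665 was near the limit of detection. Rebuilt reads summed to 67 in wild type and 98 in cfm6-1 at ATMG00060, and to 34 and 40 at ATMG00513. ATMG00665 (nad5b) was at 1.83, 3.60 and 2.70 RPKM in wild type replicates 1 to 3 and at 0.96, 0.87 and 1.72 in cfm6-1 replicates 1 to 3 (limma adjusted p = 0.0134). Its gene model is 0.022 kb long, and these values stand for 9 reads in wild type and 4 in cfm6-1, so the difference is not resolved at this depth; in limma-voom on reads rebuilt from the RPKM values the adjusted p is 0.0818. ATMG00060 (nad5c), below the filter, was at 0.82 ± 0.12 and 1.18 ± 0.43 RPKM, and ATMG00513 (nad5a) at 0.16 ± 0.03 and 0.18 ± 0.12 RPKM (n = 3); multiply mapped reads reached a share of 0.399 at ATMG00513, so its level is uncertain. The tables hold 1 value per gene model and none per intron, so the splicing of nad5 intron 4 was not measured here.

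Genes of photosynthesis fell together. Of 46 nuclear genes for photosystem, antenna and Rubisco subunits, 44 fell and 1 rose (45 and 1 adjusted over the list alone), with a median log2 change of -0.96 (camera adjusted p = 1.45e-13, and adjusted p = 0.498 with an estimated correlation). PSAD-2, a photosystem I subunit, fell from 604 ± 66.9 to 194 ± 21.7 RPKM (n = 3). NPQ4, the photosystem II subunit that dissipates excess light, fell to 54.1% of wild type, and the antenna gene Lhca6 to 40.8%. RBCS3B, a Rubisco small subunit, went from 3229 ± 307 to 1134 ± 124 RPKM; a share of up to 0.265 of its reads was multiply mapped. In photorespiration, 12 of 13 genes fell and none rose (12 and 0 adjusted over the list alone; median -0.63, camera adjusted p = 1.99e-05, and adjusted p = 0.470 with an estimated correlation). The glycine decarboxylase subunit GLDP1 fell to 39.6% of wild type and the aminotransferase AGT to 32.2%.

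Genes that rise in darkness and sugar shortage were lower in cfm6-1. In the carbon starvation list, 17 of 18 genes fell and none rose (17 fell and 1 rose adjusted over the list alone), with a median of -1.24 (camera adjusted p = 1.48e-07, and adjusted p = 0.470 with an estimated correlation). DIN10, a raffinose synthase family gene, fell from 628 ± 61.5 to 151 ± 14.0 RPKM, the beta-xylosidase BXL1 from 271 ± 28.0 to 74.4 ± 3.82, and MCCA, a leucine breakdown enzyme, to 24.5% of wild type (n = 3).

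**Figure D2:**
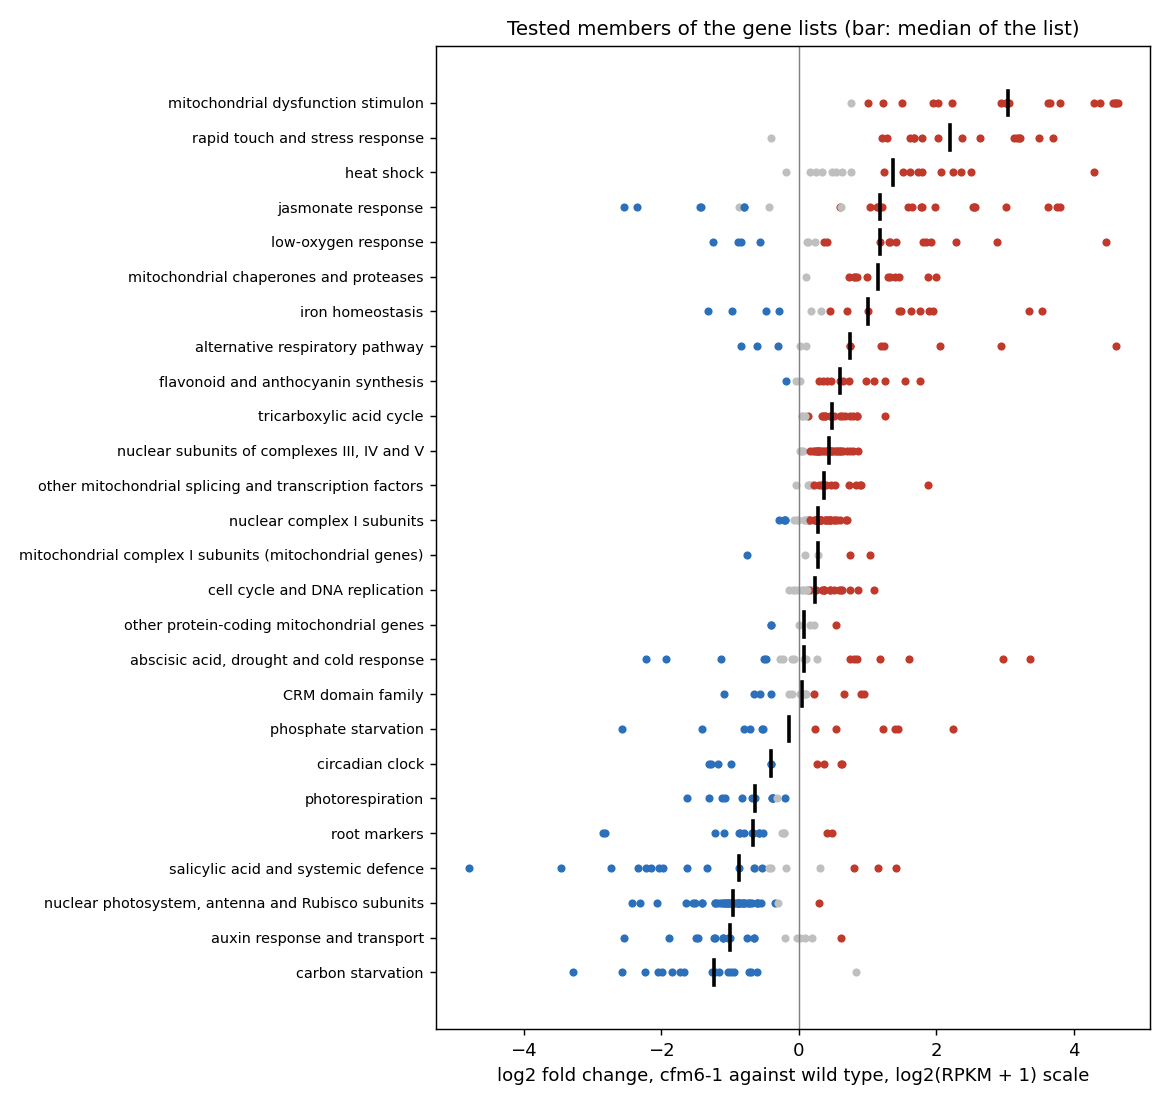
Log2 fold change of each tested member of the 26 tested gene lists, cfm6-1 against wild type, on the log2(RPKM + 1) scale. Red points rose and blue points fell at a limma adjusted p below 0.05, grey points did not pass, and the black bar is the median of the list, which runs from -1.24 for carbon starvation to 3.05 for the mitochondrial dysfunction stimulon.

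Hormone and defence groups moved in different directions. In the salicylic acid and systemic defence list, 13 of 21 genes fell and 3 rose (14 and 3 adjusted over the list alone; median -0.86, camera adjusted p = 0.000741, and adjusted p = 0.501 with an estimated correlation). PR5, a pathogenesis-related protein, fell from 37.3 ± 1.35 to 4.85 ± 1.27 RPKM, and NIMIN1, which binds the salicylic acid receptor NPR1, to 7.30% of wild type. In the jasmonate list, 17 of 26 genes rose and 6 fell (17 and 6 adjusted over the list alone; median 1.19, camera adjusted p = 0.0179, and adjusted p = 0.544 with an estimated correlation). The lipoxygenases LOX3 and LOX4, which start jasmonate synthesis, rose 14.5-fold and 16.4-fold, and the repressor JAZ1 5.92-fold. In the auxin list, 13 of 19 genes fell and 1 rose (13 and 1 adjusted over the list alone; median -0.99, camera adjusted p = 3.67e-05, and adjusted p = 0.470 with an estimated correlation). The auxin carriers PIN7 and PIN3 fell to 34.0% and 45.0% of wild type, and the auxin-induced IAA19 to 22.1%. The abscisic acid, drought and cold list was split, with 7 of 19 genes higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.972); its median of 0.07 and mean of 0.26 lie above 0 and camera points down, and the median turns to -0.02 without cfm6-1 replicate 1 and to -0.08 with a filter at 10 RPKM. CBF2, a cold regulator, rose 21.5-fold, whereas the dehydrin RAB18 fell to 16.1% and COR15B to 21.6% of wild type.

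Rapid touch and stress genes rose in 15 of 16 cases and fell in none (15 and 0 adjusted over the list alone; mean log2 change 2.24, camera adjusted p = 3.80e-05, and adjusted p = 0.498 with an estimated correlation). AT5G51190, an ERF transcription factor, rose 15.5-fold, CML38, a calmodulin-like protein, 12.3-fold, and the zinc finger gene SZF1 9.43-fold. The cfm6-1 libraries differed among themselves here: the mean log2(RPKM + 1) of the list was 6.88, 6.92 and 7.53 in cfm6-1 replicates 1 to 3, against 4.66, 5.01 and 4.94 in wild type replicates 1 to 3.

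Flavonoid and anthocyanin synthesis rose in 12 of 15 genes and fell in 1 (12 and 1 adjusted over the list alone; median 0.61, camera adjusted p = 0.0128, and adjusted p = 0.470 with an estimated correlation), with chalcone synthase TT4 up 3.56-fold and TT5 up 2.64-fold. Cell cycle and DNA replication rose in 16 of 28 genes and fell in none (14 and 0 adjusted over the list alone; median 0.24, camera adjusted p = 0.00738, and adjusted p = 0.544 with an estimated correlation). The cyclins CYCB1;1 and CYCD3;3 rose 2.50-fold and 1.90-fold. Iron homeostasis had 11 of 17 genes higher and 4 lower (11 and 4 adjusted over the list alone) and did not pass as a list (camera adjusted p = 0.111), though it does after quantile normalization (adjusted p = 0.0437). OPT3, which carries iron in the phloem, rose 3.88-fold, and AT1G47400 rose by 3.53 on the log2(RPKM + 1) scale. Phosphate starvation genes split evenly, 6 of 12 higher and 6 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.754), with a median of -0.14, which turns to 0.24 with a filter at 10 RPKM, and a mean of 0.05: the noncoding RNA IPS1 fell to 10.9% of wild type and the transporter PHT1;4 rose 2.90-fold.

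Circadian clock genes also went both ways, 4 of 10 higher and 6 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.218). CCA1, which peaks at dawn, fell to 22.8% of wild type and PRR7 to 40.2%. PRR3 rose 1.60-fold. PRR9 fell to 23.1%, with a share of up to 0.444 of its reads multiply mapped.

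Markers of single organs were compared as well. Of 18 root markers, 13 fell and 2 rose (13 and 2 adjusted over the list alone; median -0.67, camera adjusted p = 0.000463, and adjusted p = 0.498 with an estimated correlation). The root tonoplast aquaporin TIP2;2 fell from 141 ± 21.2 to 19.2 ± 4.65 RPKM and CASP1, an endodermal protein, from 39.2 ± 3.34 to 17.9 ± 1.09 (n = 3). None of the 9 seed and embryo markers reached the filter. Of 7 floral organ identity genes, 2 reached it and neither passed the test; SEP3 was at 4.79 ± 1.02 RPKM in wild type and 5.57 ± 0.64 in cfm6-1 (limma adjusted p = 0.238).

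**Figure D3:**
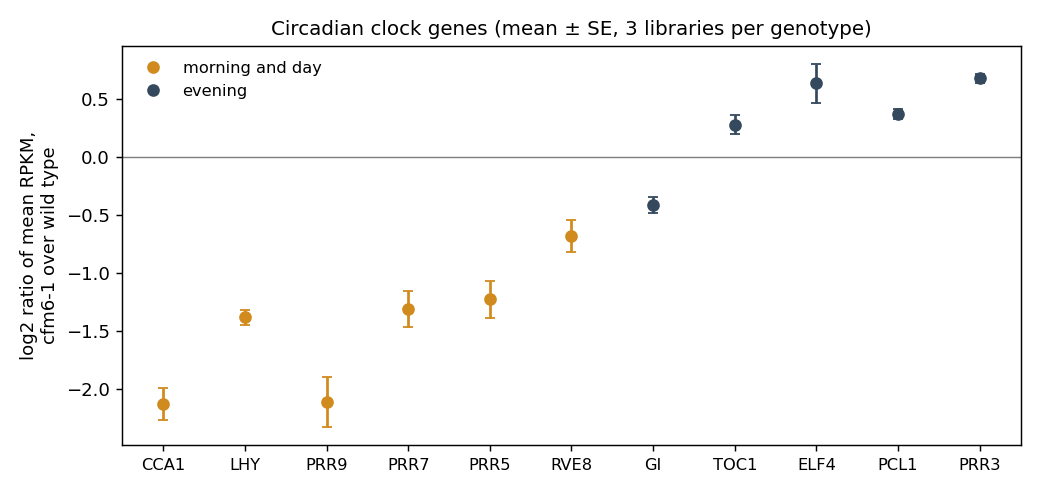
Log2 ratio of the mean RPKM of 11 circadian clock genes, cfm6-1 over wild type, with error bars of 1 SE from 3 libraries per genotype. The 6 morning and day genes lie below 0, and 4 of the 5 evening genes above it. LHY was below the filter and not tested.

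Of the 26 tested lists, 12 were called higher and 6 lower by camera with a preset correlation of 0.01, and 0 of these 18 calls hold with an estimated correlation, where 0 lists reach an unadjusted p below 0.05 either. Counts of members are to be read against all tested genes, of which 38.6% were higher and 30.2% lower, and members that respond together do not count as separate evidence.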

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

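The settings of scaling, stricter filter, rebuilt reads and shared reads were chosen after seeing the data. The counts of genes higher and lower stayed within 1.5 times of 7736 and 6063 in all settings but a pair: a filter at 10 RPKM gave 4812 and 3696, with fewer genes tested, and a log2 change of at least 1 gave 1339 and 947. Leaving out each library in turn gave 7068 to 7464 and 5491 to 5734. Quantile normalization moved the share of calls that are higher from 56.1% to 47.5%, and median-of-ratios scaling to 50.2%. With replicate number as a replicate block the counts were 7423 and 5832. To look for shared batches, the mean of its genotype was subtracted from each library, gene by gene. These deviations, not the expression values, correlated at 0.03, -0.14 and 0.00 between same-numbered libraries of the genotypes. For 0 of 3 wild type libraries was the correlation highest with the cfm6-1 library of the same number. The 12 lists called higher and 6 called lower fell to 0 and 0 with an estimated correlation. For every called list the estimate was above the preset 0.01, from 0.0153 for flavonoids to 0.828 for rapid touch and stress genes. A higher correlation weakens the test, but it was not the only source of the weaker values. The alternative respiratory list, which was not called, had an estimate of -0.0628, below the preset. Its unadjusted camera p still rose, from 0.0650 to 0.124. For flavonoids, with an estimate close to the preset, the unadjusted camera p rose from 0.00790 to 0.0617. How the loss divides between sources was not tested. fry called 15 higher and 7 lower. AT4G13070 kept its direction and its call in every setting that kept it. The mitochondrial share differed by 0.0143 percentage points between genotypes, and by 0.00128 without ribosomal RNA loci, which hold most of that signal. The plastid share differed by -0.0460 percentage points, from -0.0241 without cfm6-1 replicate 2 to -0.0819 without wild type replicate 3. The first component held 89.5% of the variance at a pseudocount of 0.1, 92.1% at 5, 89.7% without a filter, 93.2% at 10 RPKM, 91.4% without organelle loci, 92.5% without loci of shared reads, 87.4% on rebuilt reads and 91.3% to 92.0% without single libraries. Lists that did not pass changed the sign of their median: at 10 RPKM, the CRM family to -0.14, abscisic acid to -0.0797, phosphate starvation to 0.24 and the clock to 0.27; the CRM family also to -0.00555 and -0.0497 with median-of-ratios and quantile scaling; and abscisic acid, which ran from -0.0176 to 0.162 without single libraries, negative without cfm6-1 replicate 1. A filter leaves the fitted change of each gene as it was, so the medians at 10 RPKM turned because members below it dropped out. The median over all tested genes moved from 0.0495 to -0.000785 with median-of-ratios scaling and to -0.0234 with quantile normalization. The CRM median, close to 0, moved the same way. Why abscisic acid turned without cfm6-1 replicate 1 was not tested. The low-oxygen list lost its call at 10 RPKM (adjusted p = 0.178). Of the named genes, the calls that changed were ATMG00665 on rebuilt reads, ATMG01080 without wild type replicate 1 or 2, and SEP3 (AT1G24260), which passed without wild type replicate 1 (adjusted p = 0.0413). Tests that need counts (RLE factors, library totals, limma-voom on counts, count filters and DESeq2) and those for exons and introns were not run.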

Other observations

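The families and tests in this part were chosen after the results were seen. Families were drawn from symbols and product names of the reference and tested with camera among 12 such families. Genes whose names did not match were left out, so the counts are of matched genes and need not cover a whole family. Aquaporins of the plasma membrane and tonoplast fell in 13 of 16 cases and rose in 1 (median -1.28, camera adjusted p = 4.30e-05, and adjusted p = 0.536 with an estimated correlation). PIP2A went from 506 ± 21.1 to 126 ± 9.51 RPKM (n = 3), and PIP1C fell by 1.72 on the log2 scale. The family overlaps the root markers taken up below, since the 2 that fell most, TIP2;2 and TIP2;3, are tonoplast aquaporins. Their log2 ratios, -2.87 (SE 0.24) and -3.26 (SE 0.27), lie far below the median of the root markers, -0.77. Whether a lower root share bears on the family was not tested. SAUR-like auxin genes, many of them linked to cell expansion, fell in 36 of 58 cases and rose in 13 (median -0.78, adjusted p = 9.64e-05, and adjusted p = 0.536 with an estimated correlation). Xyloglucan endotransglucosylases, which remodel cell walls, fell in 17 of 25 cases and rose in 6 (adjusted p = 0.0134, and adjusted p = 0.536 with an estimated correlation): XTH6 fell by 2.68 on the log2 scale, while XTH18 rose 6.84-fold. Pentatricopeptide repeat genes, which encode organelle RNA-binding proteins, rose in 119 of 173 cases and fell in 15 (median 0.36, adjusted p = 6.26e-07, and adjusted p = 0.536 with an estimated correlation), and eukaryote-type ribosomal protein genes in 30 of 38 with 1 lower (median 0.46, adjusted p = 1.94e-05, and adjusted p = 0.536 with an estimated correlation). These medians kept their sign under median-of-ratios scaling, quantile normalization and limma-voom.

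Families without a list call still held large single changes; over all tested genes, 38.6% were higher and 30.2% lower. WRKY factors rose in 27 of 55 cases and fell in 14 (camera adjusted p = 0.378), with WRKY48 up 12.7-fold and WRKY40 up 9.71-fold. Cysteine-rich receptor-like kinases fell in 15 of 35 cases and rose in 7 (adjusted p = 0.0721). MATE efflux proteins rose in 20 of 40 and fell in 9 (adjusted p = 0.209), UDP-glycosyltransferases rose in 21 of 50 and fell in 13 (adjusted p = 0.402), and tau-class glutathione S-transferases rose in 15 of 25 and fell in 6 (adjusted p = 0.210). Expansins (6 of 18 higher, 7 lower, adjusted p = 0.401) and class III peroxidases (16 of 53 higher, 25 lower, adjusted p = 0.161) went both ways.

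Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 13799 genes and the highest other split 1, so 1 of the 10 splits called as many. For lists, the real split called 18 and the highest other split 17, and again 1 of the 10 called as many. Each other split mixes the genotypes and keeps part of their difference, so its list calls do not measure calls without a difference. Its gene calls do not either: the genotype difference then widens the spread within both groups, which by itself holds gene calls low.

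Most clock genes moved by their time of day, with an exception in the evening gene GI, which fell (log2 ratio -0.41, SE 0.07, adjusted p = 0.000974). The median of 5 evening genes rose by 0.33 (SE 0.07) and that of 6 morning and day genes fell by 1.47 (SE 0.08) on the log2 RPKM scale, a gap of 1.80 (SE 0.13). Among the morning and day genes, LHY (0.50 RPKM in wild type, 0.19 in cfm6-1) was below the filter and not tested. CCA1 (1.83 and 0.42) and RVE8 (1.85 and 1.15) were low, and PRR9 is uncertain for its multiply mapped reads. PRR7 (86.2 and 34.7) and PRR5 (28.9 and 12.3) were well above the filter and fell too. The gap is a contrast within each library from which a factor per library cancels, so its value after quantile normalization, 1.72 (SE 0.11), is no test of scaling. A later time of day at harvest of the cfm6-1 seedlings may account for the gap, since both medians moved the way this needs. That explanation was named after the pattern was seen, so the match is no test of it, and the labels give no harvest times. A clock set differently by genotype remains open as well, untested, and the falls of photosynthesis and carbon starvation genes would be read against either.

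Rapid touch and stress genes answer handling within minutes, which makes handling a candidate cause of their rise. Handling that varied from library to library, as the whole cause, would let the genotypes overlap. The lowest cfm6-1 library lay 1.87 above the highest wild type library in the mean log2(RPKM + 1) of the 16 genes. The largest range within a genotype was 0.654. The rise of the list was known before this was compared, which all but fixed the outcome, and 3 against 3 libraries separate by chance in 10% of cases. The comparison therefore does not exclude such handling, as the whole cause or as part of it. Handling that differed between the genotypes cannot be told apart from genotype, since every library of 1 genotype would share it. Within cfm6-1, replicate 3 lay 0.63 above the mean of replicates 1 and 2, so these genes do vary between like seedlings. A lasting stress state in cfm6-1 remains open and untested.

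The fall of the root markers could come from a lower share of root tissue in cfm6-1 seedlings. As the whole cause, it would move all root markers by about the same log2 ratio. Of 18 markers, 9 lay more than 2 SE from the median log2 ratio of the list, -0.77. PYK10 rose from 1720 ± 100.2 to 2408 ± 227 RPKM, a log2 ratio of 0.49 (SE 0.09), and MYB36 by 0.49 (SE 0.17). TIP2;3 fell most, with a log2 ratio of -3.26 (SE 0.27). A lower root share alone would not raise a marker, so it does not account for PYK10 and MYB36, the 2 that rose. For the markers that fell, the median comes from these same markers. Distance from it therefore cannot tell which of them a lower root share could account for. The count of 9 is above the share of 0.1 set for a whole cause, but is not the majority set against it, so it does not decide. This criterion was 1 of 3 tried in turn after the values were known, and their outcomes differed. A lower root share as part of the cause, with the median at -0.77, cannot be told apart from a change within the root, because organs were not sampled apart. No other biological explanation was tested.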
